A study of Homo sapiens with 22 samples.

How the data were processed

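Gene expression was measured by RNA sequencing in 22 libraries of enriched human blood, 12 HOneg and 10 HOpos, grouped by the sample titles. Per the labels, iChip-enriched cells were lysed, RNA was purified with a column kit and total RNA libraries were made with a rapid library kit. The deposited files hold 1 table of raw counts per library, made by the authors, with 60609 Ensembl gene IDs in each; that the values are counts was checked on the files, which hold whole numbers with totals that differ between libraries. Per the submitters' processing notes the genome build was GRCh38. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Total RNA libraries keep mitochondrial ribosomal RNA and nuclear precursor RNA, so shares of counts depend on how much of these a library holds. The authors also deposited a table of gene names.

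Gene IDs without their version were matched to a table of gene symbols, with 60295 IDs matched and 42763 carrying a symbol; positions and gene types came from GENCODE release 29 on GRCh38, which holds 58502 of the IDs and may not be the release the authors used. The authors' table gives no symbol for 11776 IDs, among them 243 of the 608 genes on the lists below. Genes of chromosome Y, XIST and TSIX, 569 in all, were left out of every test and table. No pair of libraries had identical counts, and over the 231 pairs the smallest chi-square per degree of freedom was 77.0, so each library was counted as 1 sample.

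Choices made before the data were examined were the groups, the tests, the gene lists, the alternatives and the rule for named genes. The main test was edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter by group (minimum count 10, minimum total 15), robust dispersion and the quasi-likelihood F-test of HOpos against HOneg over all 22 libraries, with Benjamini-Hochberg adjustment at 0.05. This left 9706 genes, 8957 of them protein-coding. TMM factors ranged from 0.230 to 2.78. Values are log2 CPM with a prior count of 2. Counts were scaled to the library's total over the tested genes times its TMM factor, except where library totals alone are named. The SE of a log2 fold change is the fold change divided by the square root of its F statistic.

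Gene lists covered mesenchymal and fibroblast, osteogenic, chondrogenic, BMP and TGF-beta signalling, WNT and hedgehog signalling, osteoclast lineage, endothelial, haematopoietic stem and progenitor, erythroid, platelet and megakaryocyte, neutrophil, immature neutrophil granule, eosinophil, basophil and mast cell, monocyte, dendritic cell, T cell, NK and cytotoxic, B cell, plasma cell, cell cycle, interferon response, NF-kappaB inflammatory, hypoxia and glycolysis, immediate early and heat shock, mitochondrially encoded, adipocyte, skeletal muscle, epithelial, cytoplasmic ribosomal protein and replication-dependent histone genes. The 25 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with fry, in one direction and in either, and by a permutation test of list scores, the mean log2 CPM of the list's tested genes per library. Library measures and list scores were compared with two-sided permutation tests of the difference of means with 100000 resamples (scipy 1.17.1), adjusted over the 7 measures or the 25 lists.

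The rule for named genes takes protein-coding genes with a mean log2 CPM of at least 1, the 12 with the largest fold change per direction among those that pass or, where fewer pass, those of lowest p up to 12, given as values that did not pass. Up to 4 tested members of lowest p per list may be named, with the members that pass over the list alone, and 15 genes of bone, cartilage and stromal identity regardless of result. Immunoglobulin and T cell receptor segments, HLA, KIR, genes with common inherited deletions, ribosomal RNA genes and genes without a symbol were not named.

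Alternatives were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, no low-count filter or at least 1 CPM in at least 10 libraries, DESeq2 1.42.0, limma-voom with quality weights, no robust dispersion, the total count, the erythroid score, a leukocyte score (the mean of the neutrophil, monocyte, T cell, NK and cytotoxic and B cell scores) or 1 surrogate variable (sva 3.50.0) as a covariate, abundant genes left out, protein-coding genes only, the source number as a block over sources 1 to 10 of each group, and each of the 22 libraries left out. The precision of a count is set by depth, 4269692 to 59750198 counts per library, and by the counts outside mitochondrial and haemoglobin genes, 460198 to 9454780; reads carry no stated molecular identifiers. The tests were tested on simulated data made from the real means, library sizes and dispersions with 200 changed genes. There edgeR made 2 false calls among 8556 genes tested, limma-voom 4 and DESeq2 35 among 9706. A shift of 2 log2 units in 17 T cell genes was found as a median of 1.88 with 0 other lists called. Genes were drawn independently there, while the 4 lists that passed camera in the real data had estimated inter-gene correlations of 0.17 to 0.93. The simulation thus does not show how often camera calls correlated lists falsely.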

Results

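RNA was measured in 22 human libraries of enriched blood, 12 labelled HOneg and 10 labelled HOpos. The labels give the cell content as cMPCs and blood cells, and the series title places the sources in hip arthroplasty and refers to a cMPC HO signature. Neither abbreviation is spelled out in the labels; in hip arthroplasty, HO usually stands for heterotopic ossification, the formation of bone in soft tissue. The cells were enriched on an iChip, a microfluidic device used to take rare cells from blood, and total RNA libraries were made. The libraries are numbered as sources within each group, and the labels do not state that each source is a separate donor, so p-values measure the spread between these libraries.

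The total gene count ranged from 5320519 to 59750198 in HOneg libraries and from 4269692 to 32416918 in HOpos libraries. Most counts came from a few transcripts. The mitochondrial ribosomal RNA MT-RNR2 alone held 54.4% ± 19.2 of the counts in HOneg (SD, n = 12) and 41.4% ± 16.9 in HOpos (SD, n = 10). Beta-globin, HBB, held 4.23% ± 4.86 and 9.46% ± 8.06 in the same groups. Outside mitochondrial and haemoglobin genes, 460198 to 9454780 counts remained in HOneg libraries and 1708484 to 9069661 in HOpos libraries. The medians were 2278570 in HOneg and 4556752 in HOpos, so usable depth was lower in HOneg. Genes with at least 1 count numbered 11279 ± 2667 in HOneg and 13224 ± 1752 in HOpos (permutation test, two-sided, p = 0.0613, Benjamini-Hochberg adjusted p = 0.230). Fewer than 10000 genes were detected in 5 HOneg libraries and 1 HOpos library. Haemoglobin genes together held 11.3% ± 14.9 of counts in HOneg and 21.8% ± 16.5 in HOpos (permutation p = 0.134, adjusted p = 0.234). Mitochondrial ribosomal RNAs held 56.2% ± 19.8 and 42.9% ± 17.6 (permutation p = 0.120, adjusted p = 0.234), and the other mitochondrial genes 9.02% ± 4.33 and 5.62% ± 3.70 (permutation p = 0.0657, adjusted p = 0.230). None of the 7 library measures tested passed the adjusted threshold of 0.05. The count outside mitochondrial and haemoglobin genes was not among these measures.

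**Figure D1:**
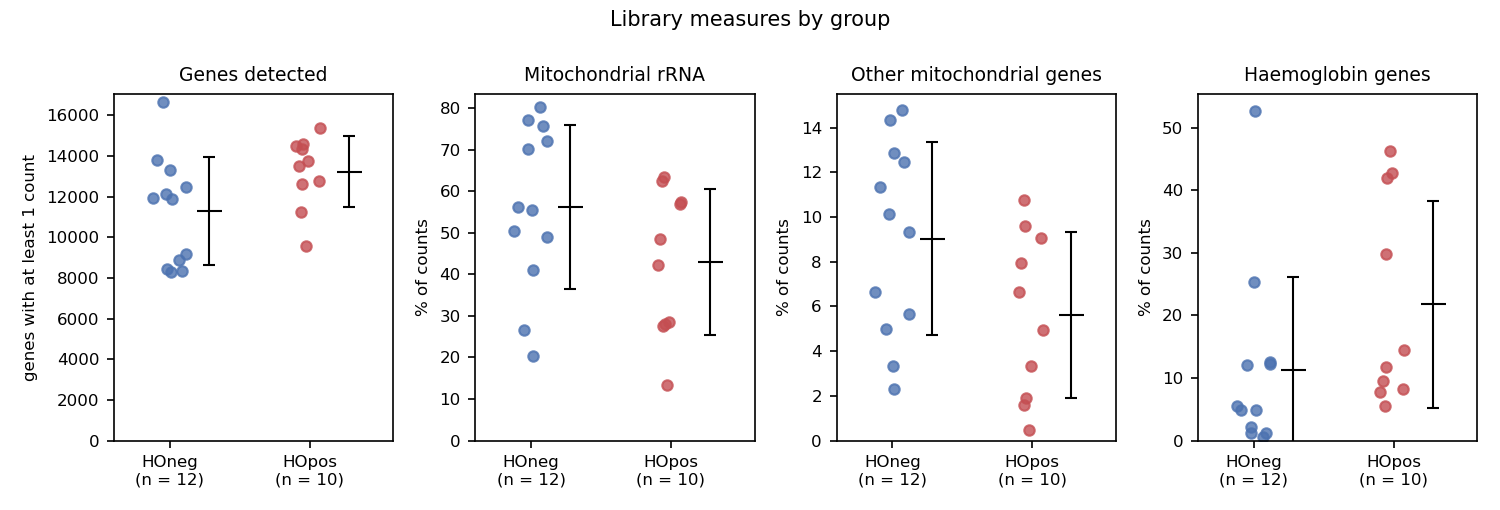
Genes with at least 1 count, and the percentage of counts from mitochondrial ribosomal RNA, other mitochondrial genes and haemoglobin genes, for each library by group. Points are libraries, and the black bars give the mean and SD (n = 12 HOneg, n = 10 HOpos), with the haemoglobin bar of HOneg ending at the axis where it would pass below 0; the groups overlap in all 4 measures, with 13224 genes on average in HOpos and 11279 in HOneg.

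The comparison of HOpos with HOneg asked which transcripts of the enriched blood differed with the HO label. No gene passed. The heat shock transcripts HSPA1B (chromosome 6, 31827735 to 31830255; log2 fold change 2.34 ± 0.64, SE), DNAJB1 (1.58 ± 0.51) and HSPH1 (1.68 ± 0.58), which encode chaperones of the stress response, were among the 12 genes of lowest p with higher values in HOpos. That set also held the ribosomal protein genes RPL32 (1.42 ± 0.41), RPS18, RPL34, RPL13A and RPL35A, the prefoldin subunit gene PFDN5 (1.24 ± 0.41), the tubulin gene TUBB2A (2.32 ± 0.70), the interferon-induced ISG15 (2.31 ± 0.80) and NXT2 (3.20 ± 1.09). NXT2 (chromosome X, 109535781 to 109544690) had counts in 4 of 12 HOneg and 10 of 10 HOpos libraries. Among the 12 genes of lowest p with lower values in HOpos were the lipid kinase gene PI4KA (chromosome 22, 20707691 to 20859417; -2.53 ± 0.65), the mitochondrial complex I genes MT-ND2 (-2.23 ± 0.68), MT-ND4L (-2.29 ± 0.71) and MT-ND5 (-2.29 ± 0.72), the T cell transcription factor gene NFATC2 (-2.96 ± 0.96), the interleukin-18 inhibitor gene IL18BP (-3.40 ± 1.06) and the endoplasmic reticulum protein gene TXNDC5 (-2.55 ± 0.84). The others were C1orf112, PKHD1L1, SPEN, CRTC1 and NPIPB5, with log2 values of -3.65, -2.45, -1.47, -4.04 and -1.67. Mean log2 CPM over libraries was 2.32 ± 3.23 (SD) in HOneg and 1.80 ± 1.42 in HOpos for NFATC2. For IL18BP it was 1.12 ± 2.89 and -0.059 ± 1.29, and for CRTC1 0.34 ± 3.24 and -1.28 ± 1.38. By this measure the groups lay closer than the fold changes of these genes. For NXT2 they lay further apart, at -1.82 ± 2.14 and 2.80 ± 0.99. By limma-voom NFATC2 was at 0.14, where the median of all genes was 0.38. By edgeR's quasi-likelihood test, 0 of 9706 genes passed, 0 higher and 0 lower, the lowest Benjamini-Hochberg adjusted p being 0.999936. At an unadjusted p under 0.05 there were 334 genes, 143 higher and 191 lower, where uniform p-values would give 485.3. Over 100 splits of the libraries into groups of 12 and 10, the real one included, the median was 318.5. The 334 genes are thus no deficit against such splits. The limma-voom test also called 0 genes, with 765 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0991. DESeq2 called 12, all of them outside the 9706 genes. HSPA1B and HSPA1A are near-identical, ribosomal protein genes and PI4KA have close processed or duplicated copies, and NPIPB5 belongs to a repeated family, so counts of these genes are uncertain.

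The spread between libraries limited what could be detected. The biological coefficient of variation was 1.25, and the median standard error of a log2 fold change was 0.84. In simulated counts with the same library sizes and dispersions, 8556 genes were tested and the edgeR test recovered 29 of 50 genes changed 16-fold, 21 of 50 changed 8-fold, 5 of 50 changed 4-fold and 0 of 50 changed 2-fold. The simulation held 9706 genes, and changed genes that the low-count filter then removed count here as not recovered. Differences of 4-fold or less were thus mostly not detectable.

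Of 80 cytoplasmic ribosomal protein genes tested, 79 had a higher value in HOpos, with a median log2 fold change of 0.95 (camera, preset inter-gene correlation 0.01, adjusted p = 2.89e-30). The call was lost with an estimated correlation (adjusted p = 0.471), and 0 of the 80 genes passed, over all genes tested or adjusted over the list alone. All 13 mitochondrially encoded protein genes had a lower value, with a median of -1.66 (camera adjusted p = 5.16e-21), among them the complex IV gene MT-CO1 at -2.08 ± 0.70. This call too was lost with an estimated correlation (adjusted p = 0.203); adjusted over the list alone 11 of the 13 genes passed, and over all genes tested 0 did. Mean log2 CPM over the ribosomal protein list was 4.37 ± 0.82 in HOneg and 5.48 ± 0.70 in HOpos (permutation test, two-sided, p = 0.00258, adjusted p = 0.0570 over 25 lists). The mean of all tested genes was itself 0.54 higher in HOpos. Relative to it, the ribosomal protein difference of 1.11 became 0.56 (permutation p = 0.0872, adjusted p = 0.726). Mean log2 CPM over the mitochondrially encoded list was 11.9 ± 1.6 and 10.5 ± 1.4 (permutation p = 0.0418, adjusted p = 0.209). This difference of -1.41 became -0.83 with library totals alone (permutation p = 0.114, adjusted p = 0.217). The median of the ribosomal protein list was 1.43 with library totals alone. That of the mitochondrially encoded list was -0.52 with library totals alone, -0.50 with genes detected as a covariate, -0.45 with a surrogate variable and -0.38 without the 6 libraries of fewer than 10000 detected genes.

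Of 17 T cell markers tested, 12 had a higher value in HOpos (median log2 fold change 0.93, camera adjusted p = 0.00202). The call was lost with an estimated correlation (adjusted p = 0.936) and with the leukocyte score as a covariate (median 0.90, adjusted p = 0.330), a mean that includes the T cell score itself and so removes part of what was tested. The higher members included CD3G of the T cell receptor complex (1.88 ± 1.19), CD6 (1.85 ± 1.17), the co-receptor gene CD8A (1.87 ± 1.27) and the homing receptor gene CCR7 (1.46 ± 1.03), none of which passed, and 0 members passed when adjusted over the list alone. The per-library list score differed by 1.63 log2 units (permutation p = 0.0381, adjusted p = 0.209), and by 1.09 relative to all tested genes (adjusted p = 0.815). The median was 0.52, 0.59 and 0.55 without HOneg replicates 3, 9 and 12 in turn. It was 0.53 with genes detected as a covariate and 0.31 with a surrogate variable. It was 1.62 with library totals alone, 1.94 with the erythroid score as a covariate, 1.98 with the source number as a block and 2.17 by limma-voom.

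The mesenchymal and fibroblast list, which holds matrix and surface markers of mesenchymal cells and fibroblasts, had 11 of 38 genes with enough counts to be tested. Of these, 9 had a higher value in HOpos (median log2 fold change 0.85, camera adjusted p = 0.0252), a call that was lost with an estimated correlation (adjusted p = 0.695). The genes of lowest p were the collagen VI genes COL6A3 (chromosome 2, 237324003 to 237414375; 1.76 ± 0.79) and COL6A2 (1.90 ± 1.24, with counts in 5 of 12 HOneg and 9 of 10 HOpos libraries, and a value of -0.40 without 1 library), the smooth muscle actin gene ACTA2 (1.24 ± 1.09) and the follistatin-like gene FSTL1 (0.89 ± 0.84). No member passed, over all genes or adjusted over the list alone. ENG, the endoglin gene, was at 0.56 ± 0.86 and the receptor gene PDGFRA at -0.39 ± 1.13. Classical stromal markers had counts in 10 or fewer of the 22 libraries and were not tested: THY1 had counts in 0 of 12 HOneg and 1 of 10 HOpos libraries, NT5E in 2 and 3, PDGFRB in 2 and 1, COL1A1 in 5 and 5, COL1A2 in 1 and 3 and CXCL12 in 5 and 4. For a gene with 0 counts in HOneg, such as THY1, the pooled HOneg counts allow up to 0.014 CPM (3 counts, counting error only). PTPRC, the pan-leukocyte marker CD45, had counts in all 22 libraries. Its log2 fold change was -0.35 ± 0.70, which became 0.068 with library totals alone, where the median of all genes was 0.27. By limma-voom PTPRC was at 0.87, where that median was 0.38. The list score differed by 1.49 log2 units (-0.080 ± 1.08 in HOneg, 1.41 ± 1.11 in HOpos, permutation p = 0.00456, adjusted p = 0.0570). The difference was 0.95 relative to all tested genes (adjusted p = 0.726) and 1.82 with library totals alone, where it passed (adjusted p = 0.0475). The list's call was also lost without HOneg replicate 5 (median 0.81, adjusted p = 0.0902), without HOpos replicate 6 (0.32, adjusted p = 0.315) and without the 6 libraries of fewer than 10000 detected genes (-0.075, adjusted p = 0.507).

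**Figure D2:**
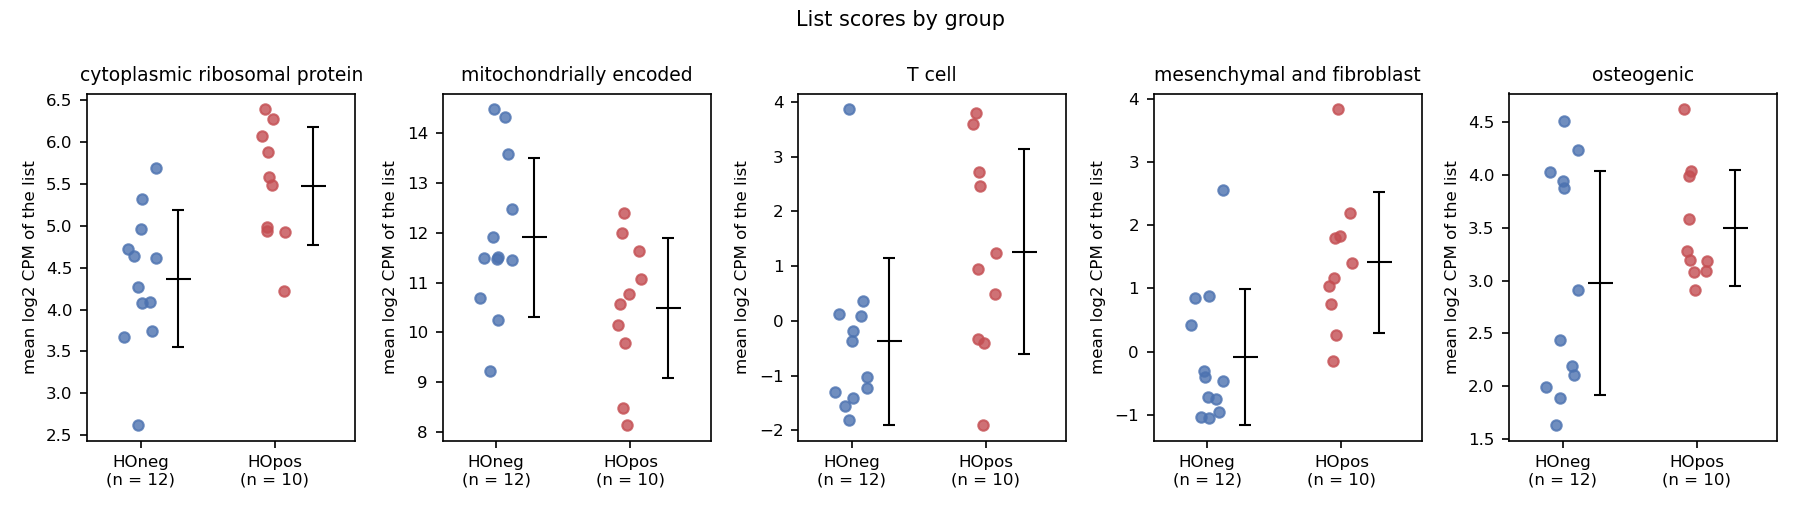
Mean log2 CPM over the tested genes of 5 lists, for each library by group. Points are libraries and the black bars give the mean and SD (n = 12 HOneg, n = 10 HOpos); the ribosomal protein mean was 4.37 in HOneg and 5.48 in HOpos, the mitochondrially encoded mean 11.9 and 10.5, and the groups overlap in every panel. The mean over all tested genes was 0.54 higher in HOpos, and relative to it the ribosomal protein difference was 0.56.

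For the osteogenic list, bone-forming genes, no difference was detected. Of its 24 genes 6 were tested, 4 with higher and 2 with lower values (median log2 fold change 0.038, mean -0.16, camera adjusted p = 0.902), and the median was -0.0094 with DESeq2 size factors, where that of all genes was -0.12. Its score differed by 0.52 log2 units (permutation p = 0.178, adjusted p = 0.494), which became -0.025 relative to all tested genes, and over the alternatives the list's value ranged from -0.42 to 0.52. RUNX2, the master transcription factor of osteoblasts, (chromosome 6, 45328157 to 45664349) was at -1.44 ± 0.99, the alkaline phosphatase gene ALPL at 0.071 ± 1.09, the matrix protein gene SPARC at 0.33 ± 0.50 and ATF4 at 0.12 ± 0.45. SP7, which encodes osterix, had counts in 0 of 12 HOneg and 1 of 10 HOpos libraries and the osteocalcin gene BGLAP in 2 and 2. SOX9, the cartilage regulator, had counts in 1 and 1, and 0 of the 18 chondrogenic genes had enough counts to be tested. Of the BMP and TGF-beta signalling genes, 16 of 23 had lower values (median -0.32, camera adjusted p = 0.212), among them SMURF2 (-2.13 ± 1.20) and SMAD1 (-1.32 ± 0.86), and the BMP receptor gene ACVR1 was at 0.18 ± 0.87. The median of the WNT and hedgehog signalling list was -0.75 (adjusted p = 0.485), that of the osteoclast lineage list -0.61 (adjusted p = 0.788) and that of the endothelial list 0.049 (adjusted p = 0.979).

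Among red cell markers, 25 of 26 had a higher value in HOpos (median 0.63, camera adjusted p = 0.0667), with HBD at 1.65 ± 0.76, AHSP at 1.34 ± 0.65 and BLVRB at 1.31 ± 0.63. Haemoglobin genes held a larger mean share of counts in that group, as given with the library measures. Of 10 plasma cell genes, 8 had a lower value (median -0.79, adjusted p = 0.0667), including JCHAIN at -3.85 ± 1.67, which was 0.81 without 1 library. TXNDC5 alone passed when adjusted over the list alone. Without HOneg replicate 5 the list median was 0.34. Of 34 replication-dependent histone genes, 24 had a lower value (median -0.31, adjusted p = 0.0667), with H4C8 at -1.78 ± 0.62. Interferon response genes were higher in 13 of 19 (median 0.23, adjusted p = 0.242), with IFI27 at 2.19 ± 0.93 and EPSTI1 at 2.12 ± 1.04. In the immediate early and heat shock list, HSPA1B, DNAJB1 and HSPH1 passed when adjusted over the list alone, HSPA1A was at 1.71 ± 0.69, and the list had a median of -0.22 and a mean of 0.014 (adjusted p = 0.490). None of these 5 lists passed in the main test. The erythroid list passed in the same direction in 21 of 42 alternatives, among them DESeq2 size factors (adjusted p = 0.0440), library totals alone (9.81e-05), the source number as a block (0.000593) and genes detected as a covariate (5.61e-11). The plasma cell list passed in 10, the histone list in 8 and the interferon response list in 2. With an estimated correlation none passed, with adjusted p = 0.979 for the erythroid list, 0.940 for plasma cell and 0.940 for histone. Without HOpos replicate 6 the erythroid median was 0.020 (adjusted p = 0.877).

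The other leukocyte lists and the remaining lists did not pass in the main test. In the same direction as there, the neutrophil list passed in 4 alternatives, 1 of them with the leukocyte score that it is part of. The BMP and TGF-beta signalling, platelet and megakaryocyte and immature neutrophil granule lists passed in 2 each and the cell cycle and NF-kappaB inflammatory lists in 1 each. The platelet and megakaryocyte list also passed in the opposite direction in 3, with medians of 0.62 without libraries under 10000 genes (adjusted p = 7.43e-08), 0.50 with genes detected as a covariate (adjusted p = 0.000209) and 0.45 with a surrogate variable (adjusted p = 0.00613). With an estimated correlation in the same fits these 3 calls were lost (adjusted p = 0.891, 0.797 and 0.875), as were the neutrophil calls (adjusted p = 0.295 to 0.875). Of 205 list calls under alternatives, 197 came from edgeR or limma-voom fits, and 0 of these held with an estimated correlation. The neutrophil list had a median of -0.034 (camera adjusted p = 0.490) with CXCR2 at -2.27 ± 1.06, the immature neutrophil granule list 0.72 (adjusted p = 0.812) with LTF at 3.47 ± 1.51, and the monocyte list -0.051 (adjusted p = 0.902) with LYZ at 1.70 ± 0.79. Medians were 0.32 for the NK and cytotoxic list (adjusted p = 0.447), -0.30 for B cell (0.902), -0.081 for platelet and megakaryocyte (0.485), 0.20 for haematopoietic stem and progenitor (0.485; mean 0.013, camera direction lower), 0.12 for cell cycle (0.902), -0.28 for NF-kappaB inflammatory (0.485), 0.027 for hypoxia and glycolysis (0.902) and 0.39 for epithelial (0.698; mean -0.030). Too few genes were tested for camera in the eosinophil (4), basophil and mast cell (3), dendritic cell (3), adipocyte (1) and skeletal muscle (1) lists, whose medians were 0.68, -0.020, -0.17, 0.42 and -1.05. The signs of the medians of the neutrophil, monocyte, B cell, platelet and megakaryocyte, endothelial, cell cycle, hypoxia and glycolysis, osteoclast lineage, BMP and TGF-beta signalling and replication-dependent histone lists turned under at least 1 other scaling.

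In all, 4 of 25 lists passed camera with the preset correlation, 0 with an estimated correlation, 0 by fry in one direction, a test of each list on its own, and 0 by the per-library scores. By fry's test for changes in either direction 1 passed, the ribosomal protein list (adjusted p = 0.0378). In 100 splits of the libraries into groups of 12 and 10, the real one included, 95 gave 4 or more lists. The median of all genes was 0.0048 with TMM. It moved to -0.12 with DESeq2 size factors, 0.27 with library totals alone, 0.38 by limma-voom, 0.39 with the source number as a block and -0.18 by DESeq2, and list medians are to be read against these shifts.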

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

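In the HOpos group of 10 libraries, 4 of 86 results had one library far from the others, measured as the gap to its neighbour over the group's whole range and set against Dixon's 95% critical value for 10 samples; chance flags about 1 in 20, or 4.3 of 86. The HOneg group, with 12 libraries, was not tested in this way. The share of counts from nuclear ribosomal RNA genes had a ratio of 0.790, at shares of 8.47e-06% ± 2.21e-05 (SD, n = 10), close to no counts. The score of the immediate early and heat shock list had a ratio of 0.468. Among named genes, SPEN log2 CPM had a ratio of 0.525 and COL6A2 log2 CPM a ratio of 0.501. The number of such results is no larger than chance gives, and none of the 4 was weighed further.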

How the results depend on the processing

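The alternatives were planned, except leaving out libraries with fewer than 10000 genes, genes detected as a covariate, list scores relative to all tested genes and an estimated correlation within each alternative, which were chosen after seeing the data. Of 3279 values under alternatives, 3005 kept their direction and side of the threshold, or for a count stayed within 1.5 times. The count of 0 genes changed held in every fit but 2, including each of the 22 fits without 1 library. Without a low-count filter edgeR called 4404 genes, 1997 higher and 2407 lower, of which 3630 had counts in 1 or 2 libraries and 71 were among the 9706 genes. Chance was not excluded for that count, since 13 of 20 splits of the libraries gave as many, the highest other 4727. DESeq2 called 12 genes, 10 higher and 2 lower, of which 0 were among the 9706 and 7 had counts in fewer than 5 libraries. Camera called 7 lists without the filter, 8 with the DESeq2 statistics, 7 with the leukocyte score, 8 with the surrogate variable and 8 with genes detected as covariates, and 0 with an estimated correlation, 0 by fry in one direction and 0 by score permutation; without 1 library the count ranged from 3 to 9, with 7 without HOpos replicate 3 and 9 without HOpos replicate 9. The cause of these shifts was not tested. No library had under 1000000 counts, so that planned exclusion gave no value.

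The mesenchymal and fibroblast list kept its direction but not its call by limma-voom (0.47), with the erythroid score (0.44), under the replicate block (1.43), with an estimated correlation (0.85), by fry (0.85) and by score permutation (1.49, adjusted p = 0.0570), and turned without libraries under 10000 genes (-0.075). Leaving out 1 library gave 0.32 to 1.18. The osteogenic median turned with DESeq2 size factors (-0.0094), without a filter (-0.17), by the DESeq2 Wald test (-0.048), with the erythroid score (-0.16), the surrogate variable (-0.094) or genes detected (-0.15) as a covariate and without libraries under 10000 genes (-0.42), and ranged from -0.088 to 0.16 without 1 library. With library totals only, 1 list score passed, the mesenchymal one (1.82, adjusted p = 0.0475), and relative to all tested genes, whose mean differed by 0.54, the osteogenic score turned to -0.025.

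The source numbers are shared by the groups. Of 10 same-number pairs, 5 had a correlation of deviations over 0.1 (range -0.18 to 0.23). Their median was 0.092, against -0.0092 for all pairs across groups, and 6 of 20 libraries matched their own number best. Each library had at least 10 libraries of the other group to match, so random matching would on average give fewer than 6. These values lean towards a likeness by number and do not exclude pairing. The main test took no account of such likeness, and its cause was not tested. The labels state no pairing, so the main test was unpaired and the source number served as a block in an alternative. The replicate block, over 20 libraries, gave 0 genes changed, 0 higher and 0 lower, 4 lists, and osteogenic median 0.18.

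Other list medians, and log2 fold changes for gene symbols, changed sign. Part of these turns lies within a shift of all genes. Relative to the median of all genes in the same fit, the direction was again that of the main test for 4 of 7 values with library totals only, 8 of 14 by limma-voom, 5 of 10 under the replicate block, 5 of 5 with DESeq2 size factors and 4 of 6 by the DESeq2 Wald test, osteogenic included. The same held for 8 of 10 score differences relative to all tested genes. In other fits few or none went back. These were 0 of 10 without libraries under 10000 genes, 0 of 6 with genes detected and 0 of 6 with a surrogate variable as a covariate. The counts were 0 of 4 without a filter, 0 of 3 with the leukocyte score and 2 of 9 with the erythroid score. They were 1 of 2 with upper-quartile factors and 1 of 2 with abundant genes left out. With protein-coding genes only 0 of 2 went back. The cause of the other turns was not tested, but that of the erythroid list with its own score as a covariate was fixed by construction. With library totals only the values became BMP and TGF-beta signalling 0.065, osteoclast lineage 0.082, platelet and megakaryocyte 0.54, monocyte 0.35, B cell 0.21, replication-dependent histone 0.34 and PTPRC 0.068. By limma-voom the values became BMP and TGF-beta signalling 0.12, WNT and hedgehog signalling 0.029, osteoclast lineage 0.68, haematopoietic stem and progenitor -0.068, platelet and megakaryocyte 0.31, neutrophil 0.48, monocyte 0.33, B cell 0.53, NF-kappaB inflammatory 0.63, immediate early and heat shock 0.28, replication-dependent histone 0.064, NFATC2 0.14, PDGFRA 0.27 and PTPRC 0.87. By the difference in per-library scores the values became BMP and TGF-beta signalling 0.22, WNT and hedgehog signalling 0.31, osteoclast lineage 0.45, platelet and megakaryocyte 0.34, neutrophil 0.31, monocyte 0.56, B cell 0.55, NF-kappaB inflammatory 0.45, immediate early and heat shock 0.31 and replication-dependent histone 0.18. Without a low-count filter the values became osteoclast lineage 0.57, hypoxia and glycolysis -0.12 and epithelial -0.47. Without libraries under 10000 genes the values became osteoclast lineage 0.22, platelet and megakaryocyte 0.62, monocyte 0.14, interferon response -0.11, hypoxia and glycolysis -0.078, replication-dependent histone 0.025, ALPL -0.48 and ENG -0.17. With DESeq2 size factors the values became endothelial -0.049, cell cycle -0.0026, hypoxia and glycolysis -0.048 and ACVR1 -0.0202. With the stricter filter the values became endothelial -0.028. With abundant genes left out the values became endothelial -0.036 and haematopoietic stem and progenitor -0.22. With protein-coding genes only the values became endothelial -0.066 and haematopoietic stem and progenitor -0.13. With the erythroid score as a covariate the values became haematopoietic stem and progenitor -0.38, erythroid -0.016, neutrophil 0.017, monocyte 0.17, B cell 0.14, cell cycle -0.18, epithelial -0.084 and PTPRC 0.017. Under the replicate block the values became haematopoietic stem and progenitor -0.39, platelet and megakaryocyte 0.15, neutrophil 0.45, monocyte 0.76, B cell 1.34, NF-kappaB inflammatory 0.40, immediate early and heat shock 0.0062, replication-dependent histone 0.053, PDGFRA 0.34 and PTPRC 0.098. With a surrogate variable the values became platelet and megakaryocyte 0.45, monocyte 0.16, NK and cytotoxic -0.37, hypoxia and glycolysis -0.20 and ALPL -0.63. With genes detected as a covariate the values became platelet and megakaryocyte 0.50, monocyte 0.10, NK and cytotoxic -0.0995, hypoxia and glycolysis -0.15 and ALPL -0.37. With upper-quartile factors the values became neutrophil 0.046 and monocyte 0.013. With the leukocyte score as a covariate the values became immature neutrophil granule -0.60, NK and cytotoxic -0.27 and ALPL -0.81. By the DESeq2 Wald test the values became cell cycle -0.0027, NF-kappaB inflammatory 0.014, hypoxia and glycolysis -0.30, epithelial 0 and ACVR1 -0.023. With total count as a covariate the values became hypoxia and glycolysis -0.027. Leaving out 1 library at a time gave ranges that cross 0 for endothelial -0.35 to 0.22, haematopoietic stem and progenitor -0.36 to 0.34, platelet and megakaryocyte -0.50 to 0.093, neutrophil -0.75 to 0.83, monocyte -0.33 to 0.31, plasma cell -1.21 to 0.34, cell cycle -0.052 to 0.28, NF-kappaB inflammatory -0.74 to 0.23, hypoxia and glycolysis -0.078 to 0.41, ALPL -0.33 to 0.66, ACVR1 -0.19 to 0.55, PTPRC -0.54 to 0.082, COL6A2 -0.40 to 2.85, ATF4 -0.039 to 0.28, JCHAIN -5.04 to 0.81. Other list medians kept their sign but moved widely. They ranged from 0.035 to 1.29 for immature neutrophil granule and 0.13 to 0.70 for interferon response. For WNT and hedgehog signalling the range was -0.88 to -0.11, and for osteoclast lineage -0.78 to -0.26.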

Other observations

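Of the 12 genes DESeq2 called outside the filtered set, 5 had counts in 5 or more libraries, and these were picked after their values were seen. The dipeptidyl peptidase gene DPP4 (CD26, a T cell surface protein) had counts in 0 of 12 HOneg and 6 of 10 HOpos libraries, NLRC3, a regulator of T cell signalling, in 2 and 8, the channel gene MCOLN2 in 3 and 9 and the pseudogene VNN3P in 2 and 6. The hexokinase gene HK2 went the other way, with counts in 11 of 12 HOneg and 4 of 10 HOpos libraries (DESeq2 log2 fold change -4.95 ± 1.11, adjusted p = 0.0218). By DESeq2 the adjusted p was 0.0496 for DPP4 and for MCOLN2, close to the threshold, 0.0339 for VNN3P and 0.0133 for NLRC3. Detection was not compared at equal depth. Fewer than 10000 genes were detected in 5 HOneg libraries and 1 HOpos library. Median counts outside mitochondrial and haemoglobin genes were 2278570 in HOneg and 4556752 in HOpos. None of these 5 genes was among those tested by edgeR with the low-count filter or by limma-voom. DESeq2 made 35 false calls in the simulated data. Only the 9706 filtered genes were simulated, so false calls among genes like these were not tested.

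The mean log2 CPM over all 9706 tested genes was itself higher in HOpos, 2.28 ± 0.30 against 1.73 ± 0.65 in HOneg (permutation p = 0.0221), so that per-library list scores carry a general difference of 0.54. Relative to that mean, 0 of 25 lists passed, and the ribosomal protein score differed by 0.56 (permutation p = 0.0872, adjusted p = 0.726), the mesenchymal score by 0.95 (permutation p = 0.0691, adjusted p = 0.726) and the mitochondrially encoded score by -1.95 (permutation p = 0.0141, adjusted p = 0.353).

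In the tests of explanations below, those on libraries with few genes detected, abundant genes, red cell RNA, the unfiltered count and the count at an unadjusted p were chosen after the result was seen. The splits cannot test the 0 genes changed, a count that all 100 of 100 splits must reach (highest other 52). Chance was not excluded for the 334 genes at an unadjusted p under 0.05, which 47 of 100 splits equalled or passed (highest other 1054), for the 4 lists, which 95 of 100 splits reached (highest other 13), for the mesenchymal median of 0.85 (27 of 100 as large in size, highest other -1.95) or for the osteogenic median of 0.038 (95 of 100, highest other 0.83). Taken singly, the ribosomal protein median of 0.95 (2 of 100, highest other 1.20) and the mitochondrially encoded median of -1.66 (4 of 100, highest other -1.71) were each reached by under 0.05 of the splits. Adjusted over the 4 list medians tested in this way these shares were 0.080 and 0.080, so chance was not excluded after adjustment. Adjusted over 25 lists, neither passed fry in one direction (adjusted p = 0.0696 and 0.263) or score permutation (0.0570 and 0.209). By fry's test for changes in either direction the ribosomal protein list passed (adjusted p = 0.0378) and the mitochondrially encoded list did not (0.788).

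The ribosomal protein list had a higher median in HOpos, a call lost with an estimated correlation. Leaving out libraries of low complexity did not lower the difference. Without those under 10000 genes the difference relative to all genes was 0.76 ± 0.33 (SE) against 0.56 ± 0.31 in all libraries. It lies above 0.5 times the full value (0.28) by more than its error, which leans against these libraries as the cause. The full difference itself did not pass (permutation test, adjusted p = 0.726), so this is weak. A few genes taking most of the counts stay open as a cause. Without them the list median was 0.92 ± 0.37 (jackknife SE over libraries) against 0.95 ± 0.31 with them, while the median of all genes moved from 0.0048 to -0.061. Both fits used TMM factors, which already limit the effect of such genes, so leaving them out could hardly move the list median. T cell RNA stays open, as the relative difference with the T cell score as a covariate, 0.54 ± 0.34, lies above 0.5 times the full value (0.28) by less than its error. A difference that goes with the HO label stays open too and was not tested apart from these.

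The mitochondrially encoded list had a lower median in HOpos, a call lost with an estimated correlation. More red cell RNA stays open. The relative difference was -1.95 ± 0.77 with the erythroid score as a covariate and -1.95 ± 0.75 without it. Relative to all tested genes, that score differed by only 0.15 between the groups, so as a covariate it could hardly change the difference. Libraries with few genes detected could account for part of it: without them the difference was -0.63 ± 0.60, which lies within its error of 0.5 times the full value (-0.98), so this cannot be told apart at 7 against 9 libraries.

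The mesenchymal and fibroblast list had a higher median in HOpos, a call lost with an estimated correlation. More platelet RNA was not decided. The relative difference was 1.01 ± 0.45 with the platelet and megakaryocyte score as a covariate and 0.95 ± 0.49 without it. Relative to all tested genes, that score itself differed by only -0.20 between the groups, so as a covariate it could hardly lower the difference. Depth stays open: with each library thinned to 460198 counts outside mitochondrial and haemoglobin genes the difference was 0.54 ± 0.33, near 0.5 times the unthinned 0.94. Libraries with few genes detected stay open as well, with 0.63 ± 0.52 without them, a value that 12.8% of 10000 random omissions of as many libraries reached or went below. With chance not excluded for this list (27 of 100 splits), a cMPC contribution remains a hypothesis that these libraries do not decide.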
